A study of Rattus norvegicus with 2 samples.

How the data were processed

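Single-cell RNA sequencing was done on IEC-6 rat intestinal epithelial cells, in 1 library labelled TNF and 1 control library, with groups taken from the sample titles. The titles also begin with different prefixes whose meaning is not given in the sources used here, so a difference between preparations cannot be told apart from the treatment. Whether TNF was still present when the cells were frozen is not given either. Per the labels' protocols, frozen cells were thawed, washed in buffered saline with albumin, counted and made into libraries with a 10K Genomics kit. The authors deposited, for each library, a matrix of whole-number counts per gene and cell with its gene and barcode lists. By these whole-number values, which sum to different totals per library, they were not normalized. Per the submitters' processing notes, the genome build was Rnor_5.0. The aligner, the counting tool, the annotation release and the filter that chose the cell barcodes are not given in the sources used here, nor is whether the counts are of unique molecules, so intervals cover counting error only, and may be too narrow if they are not. The design fixed beforehand spoke of unique molecules, and the same computations were applied to the counts as deposited.

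The lists named 16182 genes for the TNF-labelled library and 17968 for the control library, 15894 of them in both and 18256 in either, and a gene absent from 1 list was taken as 0 there. Cells were kept with at least 500 counts, 300 genes and at most 20% of counts from mitochondrial genes. This left 3457 of 3457 barcodes in the TNF-labelled library and 5712 of 5713 in the control library. Total counts were 14604393 and 24207943, so that 1 count was worth 0.0685 and 0.0413 CPM. The files hold gene names beside their Ensembl identifiers, and those names were used. No coordinates, gene lengths or GC contents were used, since the reference table at hand is of another assembly.

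Counts of the kept cells were summed per library and divided by the library's total to give counts per 1000000 (CPM). For each gene the ratio of the TNF-labelled over the control library was formed, with a library under 3 counts entered at a floor of 3 counts. The interval of a ratio is the exact conditional binomial 95% interval, that of a level the exact Poisson interval and that of a share the exact Clopper-Pearson interval. With 1 library per group there was no test between conditions, no p-value was computed, and a gene was counted by a fixed size, a ratio of at least 2 with at least 10 CPM in the higher library. The difference of shares between libraries has an interval that combines the intervals of both shares.

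Before the data were examined, 31 gene lists were fixed. For a list with at least 3 genes of a mean of 5 CPM or more, the median log2 ratio was given with its percentile among 10000 random lists matched on mean expression in 20 bins, and a list stood apart above percentile 97.5 or below 2.5. The lists were NF-kB targets, interferon response, antigen presentation, TNF signalling components, tuft cell, intestinal stem cell, pluripotency, cancer stem cell, fetal and regenerative epithelium, YAP targets, epithelial, mesenchymal, matrix proteases, S phase, G2M phase, p53 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, hypoxia response, NRF2 targets, ER stress response, handling stress, Wnt targets, Notch pathway, TGF-beta response, white blood cell, endothelial and nerve, differentiated intestinal lineages, ribosomal proteins and mitochondrial transcripts. The rule for named genes, also fixed then, took Dclk1, Tnfrsf1a, Tnfrsf1b, Mki67 and Top2a, the 10 largest and 10 smallest ratios past the fixed size without identifier-only names, ribosomal or mitochondrial genes, the 2 most different and 2 most abundant genes of each list among those with 10 CPM in either library, and up to 5 leading genes per cluster. Some genes that this rule takes are not reported here.

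Shares of cells with a Dclk1 count and cell cycle phases were computed after thinning each cell to 1700 counts, a depth set by the 20th percentile of the shallower library, with shallower cells left out. Phases were called with scanpy from the S phase and G2M lists. Clusters were made from log-normalized counts with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5, for both libraries together without integration and for each library alone, and a cluster was named only from markers fixed beforehand. Scrublet marked 0 of 3457 and 2 of 5712 cells, 0.0350% of the control cells, which was read as a failure of the caller, and doublets were left in.

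The computations were tested on simulated data for the comparison of the TNF-labelled with the control library, with 18256 genes of which 200 were changed. At 3-fold, 34 of 34 genes higher and 32 of 32 genes lower were called, at 5-fold 34 of 34 and 31 of 32, and at 1.5-fold 0 of 34 in either direction, while 0 of 7981 unchanged genes were called. Of 100 simulated unchanged lists, 5 stood apart. Both simulated libraries were Poisson draws around 1 shared profile, so they held counting noise only and no difference between preparations. These rates therefore do not give the share of false calls in the data.

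Alternatives were no cell filter, a stricter filter (1000 counts, 1000 genes, 10% mitochondrial), removal of the cells Scrublet marked, TMM factors from edgeR, scaling by the median ratio, totals without ribosomal and mitochondrial genes, the mean of each cell's CPM, thinned cells, other minimum levels, other thinning depths and other cluster settings. Leaving out the deepest 5% of cells, leaving out the low-depth cluster of each library, and keeping only cells called G1 were added after the data were seen. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.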

Results

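Gene expression was measured in single cells of IEC-6, an epithelial cell line from rat small intestine, after long-term exposure to tumor necrosis factor (TNF), an inflammatory cytokine, or to phosphate-buffered saline as control. Per the labels, treated cells received 100 ng/mL of rat TNF for 72 hours in each of 10 cycles. The series holds 1 library labelled TNF and 1 control library, so no difference between them has a replicate check, and no test between the conditions was possible. After filtering, the TNF-labelled library held 3457 cells with 14604393 counts in total and a median of 3566 counts and 1820 genes per cell. The control library held 5712 cells with 24207943 counts, and a median of 2902.5 counts and 1633.5 genes per cell. Mitochondrial transcripts made up a median of 3.46% of the counts per cell in the TNF-labelled library and 3.96% in the control library. Levels are given as counts per 1000000 (CPM) of the summed cells, and ratios as TNF-labelled over control. Every interval in parentheses is a 95% interval that covers counting error only.

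The title of the series asks whether TNF raises Dclk1, a microtubule-associated kinase used as a marker of tuft cells and of tumour stem cells, and whether it reprograms epithelial cells. Dclk1 (ENSRNOG00000032922) stood at 272 CPM (264 to 281, exact Poisson) in the TNF-labelled library, from 3978 counts, and at 249 CPM (243 to 255) in the control library, from 6023 counts. The ratio was 1.09 (1.05 to 1.14, exact conditional binomial), under the fixed size of 2-fold. With every cell thinned to 1700 counts, 36.1% (34.3 to 37.9, exact binomial) of 2728 TNF-labelled cells and 35.0% (33.7 to 36.4) of 4753 control cells held a Dclk1 count, and the difference of 1.08 percentage points had an interval of -1.19 to 3.36. The thinning left out 729 and 959 shallower cells. Without thinning the shares were 57.8% at a median depth of 3566 counts and 52.8% at 2902.5 counts. Thinned to 2900 counts, which left out 1413 TNF-labelled and 2851 control cells, the difference was 4.50 percentage points (1.64 to 7.36). No cell type that should lack Dclk1 was present, so a background share from free RNA was not measured. The ratio was 1.23 when the libraries were scaled by TMM factors, which moved the median log2 ratio of genes with at least 10 CPM in both libraries from -0.05 to 0.11.

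Other tuft cell markers were scarce in both libraries. Of the 21 tuft cell genes found, 3 reached a mean of 5 CPM, namely Dclk1 itself, Ltc4s at 6.50 against 4.75 CPM and Avil at 5.41 CPM in both libraries. The list's median log2 ratio of 0.13 was that of Dclk1, so it says nothing of other markers, and lay at the 64.1 percentile of 10000 random lists matched on expression. Such a percentile, here and for the other lists, describes these libraries and is no test of the conditions. Pou2f3, the transcription factor that specifies tuft cells, had 8 counts in the TNF-labelled library and 63 in the control library, and Trpm5, a tuft cell ion channel, had 3 and 4. Apart from Dclk1, the genes named here were singled out after their values were seen.

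Of 8550 genes with at least 10 CPM in either library, 451 were at least 2-fold higher and 700 at least 2-fold lower in the TNF-labelled library, and 7399 lay under 2-fold. For 304 of the higher and 442 of the lower genes the whole counting interval lay past 2-fold. The split depended on the scaling, since TMM factors gave 750 higher and 444 lower genes, or 62.8% higher among the genes past 2-fold against 39.2%. Across the 8550 genes the levels in the libraries correlated with a Pearson r of 0.910 on the log2(CPM + 1) scale, a value over genes, which are not independent replicates.

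The largest ratio was that of Prrx1, a homeobox transcription factor of mesenchymal cells, at 18.9 CPM in the TNF-labelled and 0.537 CPM in the control library, or 35.2 times higher (20.2 to 66.9). Fbln5, an elastic fibre protein, stood at 92.0 against 7.23 CPM (ratio 12.7, 10.9 to 14.99). Gdf6, a ligand of the bone morphogenetic protein family, had a ratio of 13.5 (8.91 to 21.4). The adhesion genes Pcdh17 and Ctnnd2 had ratios of 17.8 (10.95 to 30.6) and 9.10 (7.98 to 10.4). Npr3, a natriuretic peptide receptor, and Ldhb, a lactate dehydrogenase subunit, were 8.16 and 7.47 times higher. Fam71a and Tmem45a, also among the 10 largest, had ratios of 12.5 and 8.10.

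The smallest ratio was that of Matn4, a matrix protein of the matrilin family, with 3 counts in the TNF-labelled library and 1227 in the control library (ratio 0.00405, 0.000835 to 0.0119). Gkn2, a secreted protein of the gastric epithelium, was at 1.99 against 65.0 CPM, 32.7-fold lower in the TNF-labelled library. Zfp36, which encodes an RNA-binding protein that promotes decay of cytokine mRNAs, was at 11.02 against 214 CPM, 19.4-fold lower. Hs6st2, a heparan sulfate sulfotransferase, Serpinb10, a serine protease inhibitor, and Sytl3, a synaptotagmin-like protein, were 19.6, 17.9 and 17.1-fold lower. These folds rest on 16, 12 and 22 counts in the TNF-labelled library. Prr15, Ccdc19 and Irf2bp2 were 36.9, 35.1 and 13.4-fold lower, each from 16 counts or fewer in the TNF-labelled library. The remaining member of the 10 smallest was Ccl2.

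NF-kB target genes, which TNF receptor signalling is known to induce, were lower in the library labelled TNF. Of 23 tested, 13 were at least 2-fold lower, 3 at least 2-fold higher and 7 under 2-fold, and the median log2 ratio of -1.27 lay below all 10000 random lists, whose 95% range was -0.38 to 0.31. Ccl2, a chemokine that attracts monocytes, was at 60.9 CPM (ratio 0.0628, 0.0586 to 0.0671) against 969.8 CPM in the control library. Cxcl1, a chemokine that attracts neutrophils, was at 147 against 1502 CPM, 10.2-fold lower, and Ier3 at 861 against 1751 CPM. The 3 members that were higher, named after their values were seen, were Tnfaip3, which encodes an inhibitor of NF-kB, C3, a complement component, and Lcn2, an iron-binding acute phase protein, with ratios of 2.60, 2.51 and 2.54. Because this direction is opposite to that known induction, every direction below is given for the library labelled TNF and not for the treatment.

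**Figure D1:**
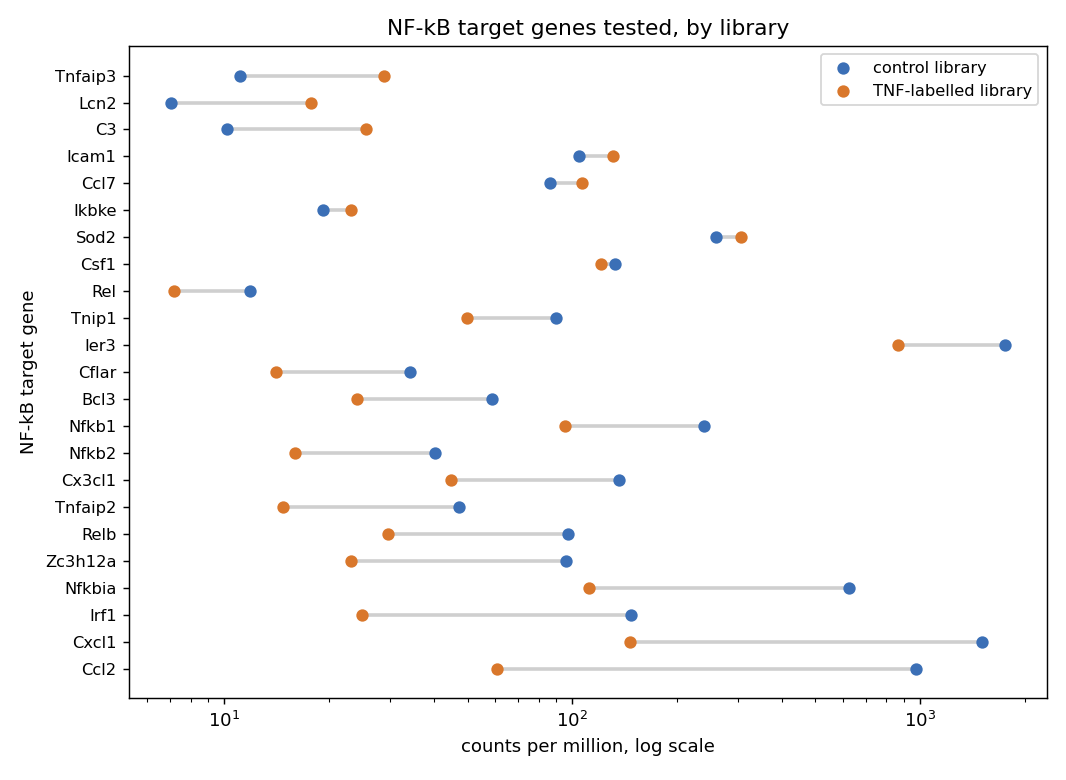
Level of each of the 23 tested NF-kB target genes in CPM on a log axis, with 1 orange point for the TNF-labelled library, 1 blue point for the control library and a grey line joining them. Ccl2 and Cxcl1 at the bottom were lowest relative to control, while Tnfaip3, Lcn2 and C3 at the top were more than 2-fold higher.

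Components of TNF signalling showed no common direction. Tnfrsf1a, the main TNF receptor of epithelial cells, was at 39.2 CPM in the TNF-labelled library and 78.4 CPM in the control library, a ratio of 0.4998 (0.454 to 0.549), and Tnfrsf1b had 1 and 6 counts. Among 19 signalling components tested, 2 were at least 2-fold higher and 1 lower, with a median log2 ratio of -0.09 at percentile 51.7. The higher ones were Xiap, an inhibitor of caspases (ratio 2.35, 2.04 to 2.71), and Cyld, a deubiquitinase that restrains NF-kB signalling (ratio 2.28, 2.04 to 2.54). Ikbkb, a kinase of the NF-kB pathway, was 1.81 times higher. Interferon-stimulated genes (30 tested, 2 higher and 1 lower) had a median of 0.01 at percentile 67.9, with Cxcl10 at a ratio of 0.432 and Ifit1lb at 2.15. Of the 654 Cxcl10 counts in the TNF-labelled library, 223 lay in 1 cluster of 26 cells. For antigen presentation (16 tested, 0 higher and 1 lower) the median was 0.03 at percentile 62.8, with B2m at 1621 against 1827 CPM and RT1-S3 3.24-fold lower.

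The list of handling stress, which joins early response and heat shock genes, was lower in the TNF-labelled library as well, with 6 of 16 at least 2-fold lower, 0 higher, and a median log2 ratio of -0.82 below all random lists. The 6 lower genes were all of the early response part. Besides Zfp36, Junb, a subunit of the AP-1 transcription factor, was at 5.14 against 58.6 CPM. Egr1 and Klf6, transcription factors of the early response, were at 293 against 561 CPM and 315 against 532 CPM. Targets of p53 (22 tested, 4 lower) had a median of -0.43 at percentile 1.64, with Gdf15 7.09-fold lower, Ccng1 at 134 against 348 CPM, and Mdm2, which encodes the ligase that degrades p53, 1.42 times higher. That list's call ended under 3 alternatives, among them cells called G1, with a median of -0.30.

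Epithelial and fetal-type genes were lower in the TNF-labelled library. Of 14 epithelial genes tested, 4 were at least 2-fold lower and 0 higher, and the median log2 ratio was -0.70 at percentile 0.180. Spint2, a membrane protease inhibitor, was at 36.7 against 140 CPM (ratio 0.262, 0.239 to 0.287) and Krt18, a keratin of simple epithelia, at 27.0 against 93.4 CPM. With each cluster found within a library set against the whole of the other library, the epithelial median stayed below 0 but ranged from -1.26, for control cluster 5, to -0.02, for control cluster 2. Krt8, the keratin partner of Krt18, stood at 2193 and 2456 CPM and Cdh1, which encodes E-cadherin, at 313 and 424 CPM. Genes of fetal and regenerative epithelium (11 tested, 3 lower) had a median of -0.70 at percentile 0.310, with Areg, a ligand of the epidermal growth factor receptor, at a ratio of 0.280 and Gja1, a gap junction gene, at 0.312. S100a6, the most abundant member, stood at 9640 and 9120 CPM, and Anxa1 at 1387 and 2250 CPM.

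YAP target genes were higher in the TNF-labelled library as a whole, with a median log2 ratio of 0.45 at percentile 99.1. With each cluster of cells found within a library set against the whole of the other library, the median ranged from -0.24, for control cluster 3, to 1.05, for TNF-labelled cluster 0, so the direction did not hold for every cluster. Of 15 tested, 3 were at least 2-fold higher and 2 lower. Ankrd1, a transcriptional cofactor, was at 23.8 against 4.75 CPM (ratio 5.02, 4.05 to 6.25), Ctgf at 447 against 328 CPM and Tgfb2 at 288 against 168 CPM, while F3, which encodes tissue factor, was 5.63-fold lower. The call was lost at percentile 97.35 with thinned cells and at 97.065 with a higher minimum level.

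Mesenchymal genes went both ways (20 tested, 2 at least 2-fold higher and 2 lower, median 0.16, percentile 86.9). Lox, an enzyme that crosslinks collagen, was at 1469 CPM in the TNF-labelled library and 325 CPM in the control library (ratio 4.52, 4.40 to 4.64), whereas Col3a1, a fibrillar collagen, was 9.69-fold lower. Vim, the intermediate filament vimentin, had a ratio of 0.598 and S100a4 one of 1.34. Matrix proteases and their inhibitors (11 tested, 3 lower) had a median of -0.50 at percentile 2.72, with Adamts1 at a ratio of 0.312, Mmp11 at 0.461, Plat at 0.572 and Timp2 at 1.12. For the TGF-beta response (19 tested, 4 lower) the median was 0.29 at percentile 95.5, with Smad7, an inhibitor of the pathway, 3.98-fold lower and Id2 3.12-fold lower.

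The lists of intestinal and cancer stem cell genes lay inside the range of random lists. Intestinal stem cell genes (7 tested, 1 lower) had a median of 0.16 at percentile 74.2, with Sox9 at a ratio of 0.442, Rnf43 at 1.94, Slc12a2 at 1.51 and Cdk6 at 1.12. Cancer stem cell genes (8 tested, 1 lower) had a median of -0.19 at percentile 31.8, with the drug efflux pump gene Abcb1a 2.39-fold lower, and Alcam and Itgb1 at ratios of 0.759 and 0.653. Only 2 of the 10 pluripotency factors found reached the minimum, too few for a median. They were Myc, a growth-promoting transcription factor, at 8.90 against 57.7 CPM (ratio 0.154, 0.128 to 0.185), and Klf4 at 757 against 1172 CPM. Wnt targets (6 tested, 1 lower, median 0.22, percentile 80.7) included Ctnnb1, which encodes beta-catenin, 2.97-fold lower, and Ccnd1 at a ratio of 1.25, and with genes down to 1 CPM their median was -0.21. Notch pathway genes (6 tested, 1 lower, median -0.49, percentile 10.9) included the Notch target Hes1 at 19.0 against 148 CPM and the receptor gene Notch2 at a ratio of 1.41, and with a minimum of 20 CPM their median was 0.28.

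Of the metabolic lists, glycolysis and cholesterol synthesis stood apart as lower. Glycolysis genes (14 tested, 2 lower and 0 higher) had a median log2 ratio of -0.54 at percentile 0.930, with Pgam1 at 394 against 986 CPM, Gapdh at 1830.3 against 3863 CPM and Aldoa at 908 against 1732 CPM. Including genes down to 1 CPM ended that call at percentile 5.58. Cholesterol synthesis genes (21 tested, 1 lower) had a median of -0.47 at percentile 0.680, with Nsdhl at a ratio of 0.511, Fdps at 0.838 and Sqle, against the direction of the list, at 1.65. Oxidative phosphorylation genes (24 tested, 3 lower, median -0.05, percentile 34.5) held both Atp5b and Cox4i1, 1.99 and 1.79 times higher, and Uqcrc2, 2.10-fold lower.

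The hypoxia, NRF2 and ER stress lists lay inside the range of random lists. Hypoxia genes (14 tested, 4 lower) had a median of -0.36 at percentile 6.11, with Bnip3 2.85-fold lower and Vegfa, the vascular growth factor gene, 2.81-fold lower. NRF2 targets (18 tested, 2 lower) had a median of -0.40 at percentile 3.14, with the peroxiredoxin gene Prdx1 at 485 against 1731 CPM, Gsta1 2.61-fold lower and the ferritin gene Fth1 at 9013 and 8624 CPM. Genes of the ER stress response (21 tested, 4 lower) had a median of -0.34 at percentile 4.21 (2.33 with thinned cells), with Dnajb9 3.92-fold lower, Pdia4 2.42-fold lower and Canx 2.36-fold lower.

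Ribosomal protein genes had a median log2 ratio of -0.42 at percentile 0.0100, below zero under all scalings tried, yet single genes lay far apart in both directions. Of 84 tested, 7 were at least 2-fold higher and 10 lower. Rps4x was at 1940 against 429 CPM (ratio 4.52, 4.42 to 4.62) and Rps15a at 4491 against 1689 CPM, while Rpl39l was 5.10-fold lower. Counts of these genes are uncertain where near-identical copies share reads. Mitochondrial transcripts (13 tested, 1 higher, median 0.01, percentile 51.5) included ND3 at 397 against 180.1 CPM and Mt-co1 at 8088 against 12995 CPM.

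**Figure D2:**
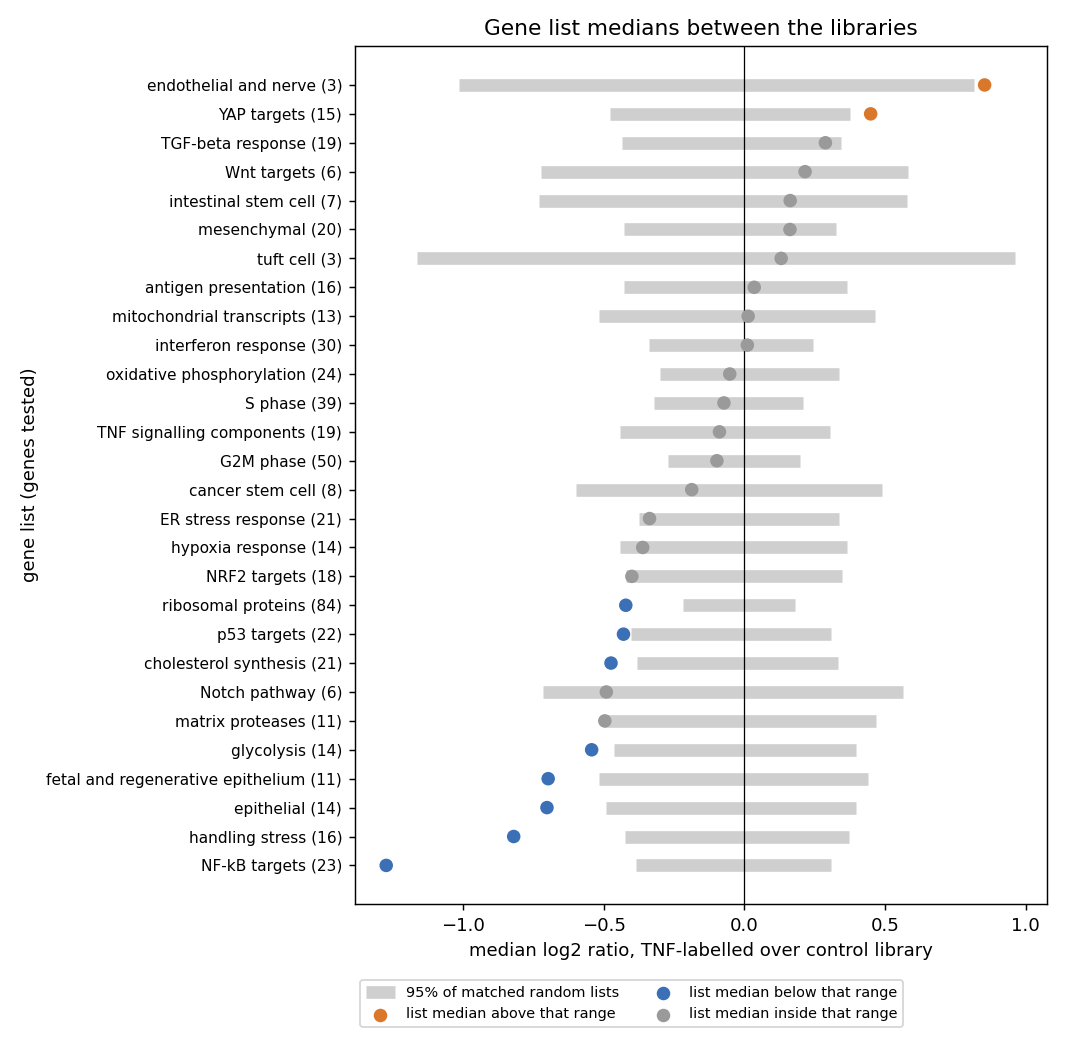
Median log2 ratio of the TNF-labelled over the control library for each gene list with at least 3 genes tested (points, number of genes in brackets), against the range that holds 95% of 10000 random lists matched on expression (grey bars). NF-kB targets lay lowest at -1.27, and YAP targets at 0.45 and the 3 endothelial and nerve genes at 0.85 lay above their ranges.

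Genes of cell division were measured alongside cell cycle phases. Mki67, a marker of proliferating cells, was at 350.2 against 296 CPM (ratio 1.18, 1.14 to 1.23) and Top2a, the topoisomerase of dividing cells, at 355 against 136 CPM (ratio 2.61, 2.495 to 2.72). Of the 5183 Top2a counts in the TNF-labelled library, 3924 lay in 1 cluster of 697 cells at 956 CPM, with the other clusters at 97.49 to 247 CPM. In the control library a cluster of 246 cells was at 499.6 CPM and the others at 76.4 to 143 CPM. S phase genes (39 tested, 2 higher and 5 lower) had a median of -0.07 at percentile 49.1, with Prim1 2.80 times and Wdr76 3.66 times higher and Cdca7 2.83-fold lower. G2M genes (50 tested, 4 higher and 4 lower) had a median of -0.10 at percentile 30.7, with Aurkb, a mitotic kinase, 3.54-fold lower and Tubb4b at 906 and 801 CPM. In cells thinned to 1700 counts, G1 was called in 42.05% (40.2 to 43.9) of TNF-labelled and 35.5% (34.1 to 36.9) of control cells, S in 14.9% and 15.4%, and G2M in 43.1% (41.2 to 45.0) and 49.1% (47.7 to 50.6). Without thinning, G1 took 43.0% and 35.2%, S 19.6% and 20.6%, and G2M 37.3% and 44.2%. Thinned to 2900 counts, which kept 2044 TNF-labelled and 2861 control cells, G2M took 37.2% and 40.7%. The difference was -3.54 percentage points (-6.32 to -0.739) against -6.08 at 1700 counts. About 25.1% and 24.3% of the thinned cells had their higher phase score within 0.05 of the cut between G1 and the other phases. Cells near the boundary between S and G2M were not counted. The phase scores read free RNA as well, and no rate of cycling was read from these calls.

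Few genes of other cell types reached the minimum level. Only 1 of 15 white blood cell genes reached the minimum, Cd14, a co-receptor for bacterial lipopolysaccharide, at 36.9 against 102 CPM. Of 15 endothelial and nerve genes, 3 were tested, and the list stood apart as higher in the TNF-labelled library (median 0.85, percentile 97.9). Tek was at 127 against 70.5 CPM and Mbp at 11.2 against 24.99 CPM, while with genes down to 1 CPM the median was -0.06. The call held in 7 of 13 alternatives, and in some of the others too few genes were left. For differentiated intestinal lineages 2 of 22 genes were tested, Pla2g2a at 624 against 478 CPM and Agr2 3.61-fold lower. Epcam, an epithelial adhesion gene looked up after the data were seen, had 4 counts in each library.

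When cells of both libraries were clustered together, each of the 7 clusters held over 90% of its cells from 1 library. In the neighbour graph built with 15 neighbours, cells are also linked to those that count them as neighbours. Of a cell's linked cells, a mean of 98.4% for TNF-labelled and 99.2% for control cells came from its own library. Such clusters cannot be told from their library, and no shares of clusters were compared between the libraries. Genes leading the joint clusters made of TNF-labelled cells included Adamts9, Sulf1 and Prrx1.

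Within each library, 6 clusters were found. In the TNF-labelled library a proliferating-like cluster of 697 cells (20.2%) was led by Kif14, Prr11, Mxd3, Sgol1 and Top2a, with 9 of 10 proliferation markers asked for at least 2-fold above the remaining cells. The control library held a proliferating-like cluster of 246 cells (4.31%) led by Top2a, Nusap1, Mxd3, Aurka and Esco2, also with 9 such markers. Because each library was clustered alone, these shares were not compared. Another 26 TNF-labelled cells (0.752%) were led by Ifit3, an interferon-stimulated gene, at 640.5 CPM, and held the chemokine gene Cxcl10 at 1957 CPM. Ifit2 and Rsad2, also of the interferon list, were among their leading genes at 386 and 132 CPM. Irg1 and Rtp3 ranked above these by fold, but at 17.5 and 35.1 CPM. Both rest on very few counts, since the cluster held 113978 counts in total. A control cluster of 548 cells (9.59%) was led by Tchhl1, Lypd8 and Mal and held Lgals4, a galectin of intestinal epithelium, at 641 CPM. Control cluster 0, with 1496 cells (26.2%), had a low median depth of 1844 counts and a median mitochondrial share of 5.75%, and TNF-labelled cluster 3, with 578 cells, a median depth of 1575.5 counts. The remaining clusters stayed unnamed, among them a TNF-labelled one of 824 cells led by Lgr5, an intestinal stem cell marker, at 40.6 CPM.

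Dclk1 was found in every cluster found within a library, from 226 to 333 CPM in the TNF-labelled and from 174 to 298 CPM in the control library. Cells with a Dclk1 count were compared with cells without one at 1700 counts each. In the TNF-labelled library, 985 cells with the count had S phase genes slightly lower (median log2 ratio -0.18, below all random lists), G2M genes lower (-0.12) and mesenchymal genes higher (0.15, percentile 99.955). The interferon list was at 0.13, at percentile 99.87. In the control library the interferon list was at 0.02. The hypoxia and ER stress lists were at -0.11 and -0.07 in the control library and at -0.01 and -0.04 in the TNF-labelled library, and these differences between the libraries were not tested. Corresponding values for the 1665 control cells with the count were -0.08 for S phase, -0.08 for G2M and 0.14 for mesenchymal genes. A Dclk1 count was found in 39.6% of G1, 29.3% of S and 35.1% of G2M cells of the TNF-labelled library, and in 37.4%, 33.4% and 33.9% in the control library.

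**Figure D3:**
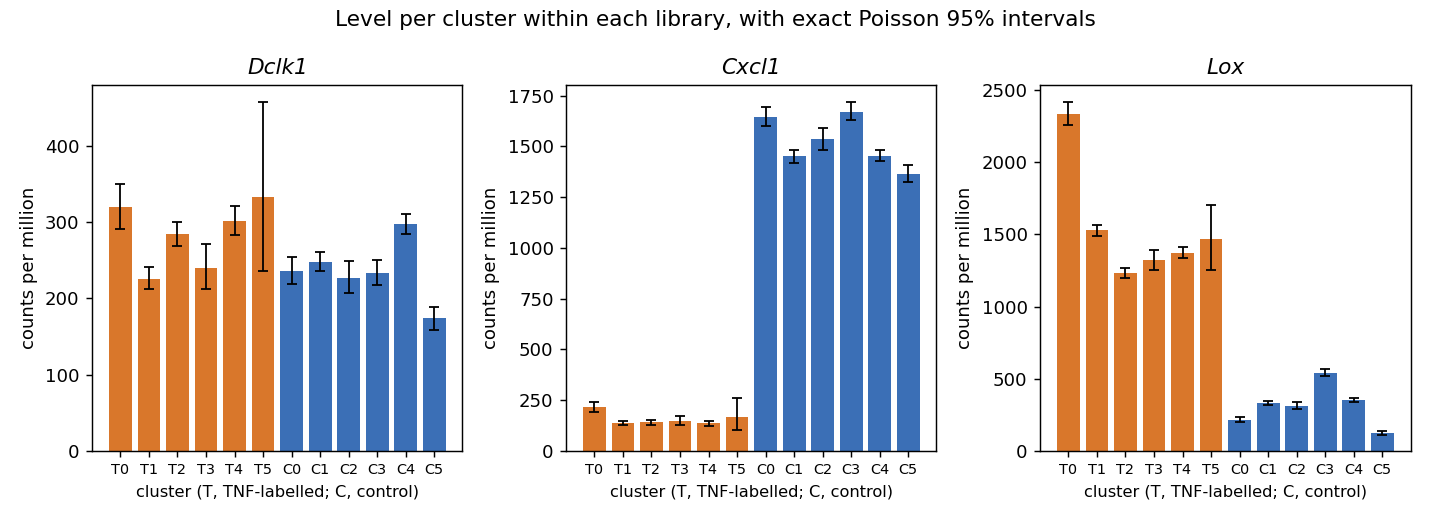
Level of Dclk1, Cxcl1 and Lox in CPM in each cluster found within the TNF-labelled library (orange, T0 to T5) and the control library (blue, C0 to C5), with exact Poisson 95% intervals. Dclk1 overlapped between the libraries, Cxcl1 was lower and Lox higher in every TNF-labelled cluster than in any control cluster.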

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

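Leaving out the deepest 5% of cells or the low-depth clusters, and keeping only G1 cells, were chosen after the data were seen. No paired analysis was possible because each group has 1 library. Of 412 recomputed values, 387 kept their side of the threshold or lay within the limits set for them, and for those that did not the cause was not tested except where given. Some alternatives could hardly change a value, since removing the filter restored 1 cell and Scrublet marked 2 cells. The other scalings of the totals shift every log2 ratio by the same amount. They could change a list's call only through the minimum level and the bins. TMM scaling gave 750 genes at least 2-fold higher and 444 lower, against 451 and 700. All 451 and 444 were shared with the main counts, by construction, since TMM multiplies every ratio by the same factor. The Dclk1 ratio was then 1.23, and matrix proteases were apart at a median of -0.33. The mean of each cell's CPM gave a Dclk1 ratio of 1.15, matrix proteases apart at -0.63, and endothelial and nerve genes no longer apart at 0.89. A minimum of 1 CPM gave 745 higher and 1687 lower genes and one of 50 CPM 221 and 339, by construction, since more or fewer genes could pass. At a mean minimum of 1 CPM, p53 targets (-0.43) and glycolysis (-0.42) were no longer apart, and endothelial and nerve genes turned to -0.059. Some lists inside the random range in both settings also changed sign, among them Wnt targets (-0.21 at 1 CPM) and the Notch pathway (0.28 at 20 CPM). At 20 CPM, YAP targets (0.43) were no longer apart and ER stress (-0.38) was. With thinned cells YAP targets (0.39) were no longer apart and ER stress (-0.38) was. The p53 targets also ended at -0.40 without the deepest cells and -0.30 in G1 cells, and endothelial and nerve genes at 0.83 without low-depth clusters and 0.79 in G1 cells. The difference in the share of cells with a Dclk1 count was 5.06 percentage points without thinning and 4.50 at 2900 counts against 1.08, and the G2M difference was -3.54 at 2900 counts against -6.08. NF-kB targets stayed apart under every alternative, those that could hardly change the call included, with medians from -1.33 to -1.11. Too few genes were left for Wnt, tuft, and endothelial and nerve lists at 20 CPM, for tuft genes in G1 cells, and for endothelial and nerve genes without the deepest cells. Of 126 other named genes, the ratio of 78 left its counting interval under TMM scaling and that of 1 under the stricter filter. No named gene that passed the fixed size changed direction under any alternative. The other scalings could not reverse such a gene, since their common shift was far smaller than 2-fold. Depth limits low genes, since 1 count was worth 0.0685 CPM in the TNF-labelled library.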

Other observations

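All tests of explanations below were chosen after the results were seen. The division of the handling stress list was also made then. It held 11 immediate-early genes at a mean of 5 CPM or more, which cells switch on within minutes of many stimuli, and 6 of them were at least 2-fold lower in the TNF-labelled library with 0 higher. Dusp1, a phosphatase of MAP kinases, was at 82.9 against 316 CPM, Fos at 72.2 against 225 CPM and Atf3 at 96.5 against 249 CPM, while Jun stood at 21.4 and 19.0 CPM. The 5 heat shock genes tested, in contrast, had a median log2 ratio of 0.14 at percentile 68.9 of random lists, with Hsp90aa1 at 427 and 388 CPM.

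Several genes that separated the libraries did so in every cluster of each. Ccl2 ranged from 50.6 to 254 CPM over the clusters of the TNF-labelled library and from 884 to 1125 CPM over those of the control library. Nfkbia, which encodes an inhibitor of NF-kB, ranged from 99.2 to 145 CPM and from 584 to 679 CPM. Zfp36 ranged from 8.77 to 19.0 CPM and from 193 to 240.3 CPM, and Matn4 from 0 to 0.660 CPM and from 30.2 to 68.4 CPM. Fbln5 was higher in every TNF-labelled cluster, at 49.7 to 359 CPM against 1.69 to 11.7 CPM, whereas Prrx1 ranged from 0 to 34.2 CPM and from 0 to 1.72 CPM. Its 0 in the TNF-labelled library was that of the cluster of 26 cells, with an interval of 0 to 32.4 CPM. In the other TNF-labelled clusters Prrx1 lay at 13.6 to 34.2 CPM, above every control cluster.

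The lower NF-kB targets in the library labelled TNF did not come from its shallow cells or those of the control library, since without the low-depth clusters the median log2 ratio was -1.28 and the 95% range of random lists ended at -0.37. A general early response that differed between the preparations, as handling between thawing and lysis can set off, stays open. Immediate-early genes outside the NF-kB list, seen to be low before they were set apart, had a median of -1.29 but heat shock genes one of 0.14. Since immediate-early genes answer many stimuli, their lower level cannot tell handling from a difference in the response to TNF. That the labels of the libraries were exchanged stays open as well, because no mark of TNF exposure independent of the NF-kB response was at hand, and 3 members of the list, among them Tnfaip3, were at least 2-fold higher in the TNF-labelled library. A lasting change of the cells after repeated TNF, such as a weaker response to it, also stays open and was not tested, and the sources used here do not say whether TNF was still present at harvest.

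Ribosomal protein genes differed from one another between the libraries with an SD of 0.82 over the log2 ratios of 84 genes, close to that of random lists matched on expression (median 0.71). Counting noise does not account for it, since none of 1000 binomial draws exceeded 0.09. A different mix of the clusters found does not either. Any mix of 1 library's clusters of at least 100 cells left an SD of at least 0.79 over 84 genes against the other library. Cell states present in only 1 library were not covered, and each joint cluster came almost wholly from 1 library. Reads shared between gene copies may contribute and cannot be told apart from a difference between the library preparations, since 67 genes without a listed copy had an SD of 0.78 but unnamed copies were not counted.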
